A study of Homo sapiens with 12 samples.

How the data were processed

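Human umbilical vein endothelial cells were held in starvation medium for 12 h in 6 groups (vehicle, TNF-α at 10 ng/mL, AdipoRon at 5 µM, SKI-I at 5 µM, TNF-α with AdipoRon, TNF-α with SKI-I), with 2 libraries per group and 12 in all. Total RNA was extracted with RNAiso Plus and libraries were made with the NEB Ultra II directional kit. The labels name the inhibitor in 2 ways, SKI-I and ski-1, read here as the same compound. They do not say whether replicates were separate cultures or donors. No pairing of libraries by replicate number was seen across groups (correlations of replicate differences -0.116 to 0.135). A shared origin with little effect on expression would not show there. Groups were taken from the sample labels.

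The deposited table holds a signal per gene: normalized counts that the authors made on a scale where the median of each library's ratios to the geometric mean over genes is equal, between 1.0073 and 1.0078. Per the submitters' processing notes Salmon, DESeq2 and GRCh38.p13 were used. Their versions and their roles are not given in the sources used here. The values are not whole numbers and low values do not fall on 1 step per library, so a factor per gene and library appears to have been divided out and whole reads could not be recovered. The table lists 22702 genes, of which 18272 have a symbol and 4430 do not, 17531 are above 0 in all 12 libraries, and the lowest sum over libraries is 8.78, so low genes had been removed before deposit. Genes of the Y chromosome and the transcripts that mark X inactivation were left out. No coordinates are given, since the annotation release used by the authors is not stated.

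Library totals were 29.7 to 38.3 M normalized counts (M, mega). A read was worth roughly 0.8001 to 1.32 normalized counts, taken from the commonest low value of each library. That puts the reads counted in the genes kept at about 27.2 to 38.2 M, lowest in TNF replicate 1 and highest in vehicle replicate 1. Since low values do not fall on 1 step, these are rough estimates and not the sequencing depth. Between 988 and 1984 genes were at 0 per library, and the 10 most abundant genes held 7.73 to 8.67% of the counts.

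Values were put on the scale log2(value + 1), so folds of genes with low values are understated. Genes with a mean of at least 10 over 12 libraries were tested (15884), with limma 3.58.1 in R 4.3.3: a model with 1 mean per group over all 12 libraries, 6 residual degrees of freedom, moderated variances with a trend, and Benjamini-Hochberg adjustment per comparison with calls at an adjusted p of 0.05. The median residual SD was 0.114. Folds are limma's, and levels are means ± SD of normalized counts with n = 2. Comparisons were each agent against vehicle, each combination against TNF-α alone and against vehicle, the difference between each compound's effect with and without TNF-α (interaction), and the compounds against each other. Comparisons that share a control group were not correlated or overlapped.

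Fixed gene lists (31) were tested with camera in limma at a preset correlation of 0.01, adjusted over 29 lists and 7 comparisons (203 tests), and again with an estimated correlation. Of 203 tests 83 passed, and 22 with an estimated correlation. In none of the called lists did median, mean and test differ in sign. The lists were leukocyte adhesion, chemokines and cytokines, NF-kB pathway and feedback, TNF superfamily, interferon response, MHC class I, coagulation, vascular tone, endothelial identity, sphingolipid metabolism, adiponectin and AMPK, fatty acid oxidation, cholesterol, fatty acid synthesis, ATF4 stress, ER chaperones, heat shock, NRF2, cell cycle, p53, hypoxia and glycolysis, lysosome and autophagy, matrix and proteases, TGF-beta response, markers of other cells (smooth muscle and fibroblasts, leukocytes, epithelium, erythroid), and signs of RNA quality (mitochondrial, ribosomal protein and histone transcripts). Epithelium and erythroid had fewer than 5 measured genes and were not tested. For the TNF-α response, genes that changed at least 2-fold were chosen with the libraries of the other compound, and 4 sets were tested with camera. Their adjustment over the 4 sets was chosen after the unadjusted values had been seen.

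Groups, comparisons, lists, the rule for named genes and the alternatives were set before the data were examined. Named genes are, per comparison of groups, the 10 highest and 10 lowest log2 changes among genes with a symbol, an adjusted p under 0.05, a mean of at least 50 and no overlap between the groups' libraries, the 5 highest and 5 lowest per interaction, up to 4 members per list, and a panel of 12 (SELE, VCAM1, ICAM1, CCL2, CXCL8, NFKBIA, TNFAIP3, SPHK1, SPHK2, S1PR1, ADIPOR1 and ADIPOR2). Not every gene the rule names is printed. The alternatives were a pseudocount of 5, no filter, quantile normalization, only the groups compared, a replicate block, robust variances, an estimated correlation for lists, and leaving out each library in turn. The fit was tested on simulated data: among 15884 genes it recovered 82% of 100 genes changed 2-fold and 53% of 100 changed 1.5-fold, with 4 unchanged genes called. The changed genes had mean levels above about 50 and changed in the AdipoRon group alone. Noise was normal, independent between genes and set by each gene's level, so these rates need not hold for the real data. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.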

Results

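Gene expression was measured by sequencing of total RNA in human umbilical vein endothelial cells (HUVECs), primary cells from the inner lining of the umbilical vein that serve as a model of vascular endothelium. The cells were held in starvation medium for 12 h. They received vehicle, the inflammatory cytokine TNF-α (10 ng/mL), AdipoRon (5 µM) or SKI-I (5 µM). AdipoRon is a small molecule that activates the adiponectin receptors, and SKI-I is a sphingosine kinase inhibitor. A further pair of groups received TNF-α together with AdipoRon or with SKI-I. Each of the 6 groups held 2 libraries, and the stated aim was to find what each agent and each combination did to the transcriptome. The labels do not say whether the 2 libraries of a group came from separate cultures or donors, so each p-value measures only the spread between these samples, which may be technical.

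The libraries held between 29.7 and 38.3 M normalized counts (M, mega). The low values put the reads counted in the genes kept at roughly 27.2 to 38.2 M per library. Libraries of the same group correlated at a Pearson r of 0.986 to 0.989 across genes, which are not independent replicates. Their median squared difference was 3.29 to 4.77 times the counting noise, estimated with the same rough worth of a read. That does not say whether they were separate cultures. Of the 12 measured genes of smooth muscle and fibroblasts, collagen gene COL1A2 reached 2174 ± 143 normalized counts in vehicle cells and COL3A1 reached 1535 ± 33.3 (SD, n = 2). Among 18 leukocyte genes 5 were measured, 3 of 14 epithelial genes were measured, and none of 10 erythroid genes was measured (0 of 10). The epithelial genes EPCAM, ESRP2 and KRT15, named after their values were seen because no other gene of that list was measured, stood at 15.2 ± 0.628, 19.3 ± 7.48 and 11.5 ± 6.2 normalized counts in vehicle cells (SD, n = 2).

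The first comparison asked what TNF-α did by itself. The leukocyte adhesion receptor E-selectin (SELE, ENSG00000007908.16) rose 531-fold, from 632.7 ± 44.6 to 335900 ± 43.3 normalized counts (SD, n = 2 per group). VCAM1 rose 174-fold and ICAM1, which also binds leukocyte integrins, rose by 6.65 on the log2 scale. The neutrophil chemokine CXCL8 rose 498-fold and the monocyte chemokine CCL2 rose 21.5-fold, from 2859 ± 159 to 61410 ± 447 (SD, n = 2). Of 30 measured chemokines and cytokines 27 rose and 2 fell, with a median log2 change of 5.83, and CSF2, CXCL10 and CXCL3 were among the 10 genes that rose most. The TNF gene itself was listed at 0 in both vehicle libraries and stood at 456.2 ± 30 normalized counts with TNF-α (SD, n = 2).

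All 28 measured genes of the NF-kB pathway and its feedback rose with TNF-α (median log2 change 2.67), among them the inhibitor NFKBIA by 7.42-fold, the ubiquitin-editing enzyme TNFAIP3 by 21.0-fold and the adaptor TRAF1 by 91.9-fold. All 45 measured interferon response genes rose (median 3.56), led by MX2, which went from 8.41 ± 1.24 to 4744 ± 198 normalized counts (SD, n = 2), with MX1 98.0-fold, IFIT1 95.5-fold and RSAD2 88.0-fold higher. All 20 genes of MHC class I antigen presentation rose (median 1.78), with HLA-F 27.7-fold and the peptide transporter TAP1 9.60-fold higher. In the TNF superfamily list 20 of 21 genes rose and 1 fell (median 1.29), including LTB, which rose 238-fold. Tested as lists with camera in limma, the chemokines (adjusted p = 2.89e-14, and 0.0181 with an estimated correlation), NF-kB genes (9.63e-20, and 0.0181) and TNF superfamily (2.06e-08, and 0.0343) passed both ways. The interferon list passed with the preset correlation (adjusted p = 7.17e-28) and not with an estimated one (adjusted p = 0.0574), as did MHC class I (4.68e-15, against 0.0694).

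Genes of endothelial identity moved down more often than up with TNF-α: 21 of 35 fell and 8 rose (median -0.32). The sialomucin EMCN fell to 533.1 ± 37.9 from 4770 ± 4.48 normalized counts (SD, n = 2), MMRN1 was 3.17-fold, CLEC14A 3.12-fold and the transcription factor SOX18 3.11-fold lower. The genes that fell most included the inhibin subunit INHBB, the noncoding RNA H19, the water channel AQP1 (111-fold lower), the gap junction gene GJA4 (69.5-fold lower) and the cytokine IL33 (35.6-fold lower). Thrombomodulin (THBD), which restrains clotting, was 10.8-fold lower, while tissue factor (F3), which starts clotting, was 12.6-fold higher. The coagulation list as a whole, with 10 of 21 genes up and 7 down, did not pass (camera adjusted p = 0.625). Neither did vascular tone (8 up and 10 down of 21, adjusted p = 0.426), in which the prostaglandin synthase PTGS2 rose 27.3-fold. The endothelial identity list passed with the preset correlation (adjusted p = 0.00584) and not with an estimated one (adjusted p = 0.249), and the adhesion list behaved alike with 12 genes up and 6 down of 19 (0.0152, against 0.249).

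Stress and metabolic genes also moved with TNF-α. Of 17 chaperones of the endoplasmic reticulum (ER) 16 rose (median 0.95), HSPA5 by 2.21-fold and SDF2L1 by 3.26-fold, and 12 of 15 heat shock genes rose and 2 fell (median 0.69), with HSPA1A 2.61-fold higher. These lists passed both ways in camera (adjusted p = 2.83e-09 and 0.000106, with an estimated correlation 0.0352 and 0.0394). In the ATF4 stress response, which supports amino acid supply, 27 of 30 genes rose and 1 fell (median 1.31), with the asparagine synthetase ASNS 11.7-fold higher. Of 36 cell cycle genes 29 fell and 1 rose (31 and 1 adjusted over the list alone, median -0.87), CENPF by 3.0-fold and TOP2A by 2.43-fold. The ATF4 list (adjusted p = 3.76e-11, and 0.115 with an estimated correlation) and the cell cycle list (2.83e-09, against 0.0844) lost their call when the correlation was estimated.

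Among the smaller shifts with TNF-α, 15 of 25 hypoxia and glycolysis genes rose and 2 fell (median 0.39), with PFKFB3 4.88-fold higher. Of 25 cholesterol genes 18 rose and 4 fell (median 0.35), with HMGCS1 2.02-fold higher. Of 15 fatty acid synthesis genes 10 rose and 1 fell (median 0.33), and of 18 NRF2 genes 11 rose and 3 fell (median 0.42). These 4 lists passed camera with the preset correlation (adjusted p = 0.000874, 0.000171, 0.00531 and 0.0201) and not with an estimated one (adjusted p = 0.4, 0.292, 0.0844 and 0.506). Under quantile normalization the fatty acid synthesis and NRF2 lists lost their call (adjusted p = 0.363 and 0.136). Cytosolic ribosomal protein genes, watched as a sign of RNA quality, were lower in 20 of 35 and higher in 1, by a median of -0.12 (adjusted p = 0.00044, and 0.642 with an estimated correlation). The lists for sphingolipid metabolism (20 up and 11 down of 42, adjusted p = 0.362), adiponectin and AMPK signalling (6 and 5 of 18, 0.883, median 0.07 and mean -0.19), fatty acid oxidation (7 and 8 of 25, 0.726), p53 targets (16 and 7 of 27, 0.098), lysosome and autophagy (12 and 11 of 30, 0.857), matrix and proteases (16 and 9 of 27, 0.167) and TGF-beta response (12 and 7 of 28, 0.462) did not pass. Nor did smooth muscle and fibroblasts (1 and 6 of 12, 0.0601), leukocytes (2 and 0 of 5, 0.4), mitochondrial transcripts (9 and 1 of 13, 0.0848) and replication-dependent histones (3 and 0 of 10, 0.844). SPHK1, a kinase that makes sphingosine 1-phosphate, rose 2.33-fold from 2090 ± 21.4 to 4870 ± 132 normalized counts, and its receptor S1PR1 rose 1.42-fold (SD, n = 2). The other sphingosine kinase, SPHK2, was called lower, at 578.2 and 561 with TNF-α against 668.1 and 740.9 in the vehicle libraries. That call did not hold in every fit without 1 library.

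In all, limma called 9094 of 15884 genes for TNF-α at an adjusted p under 0.05, with 4800 higher and 4294 lower, and 1380 of these were up and 1538 down by at least 2-fold. Under quantile normalization the larger side turned, with 3962 higher and 4859 lower. For the lists above other than the cell cycle list, the counts adjusted over the list alone differed from those over all genes by at most 1 gene in each direction. Each of the 20 genes named by size kept its call in all 12 fits that left out 1 library. Against vehicle, the combination of TNF-α with AdipoRon called 8724 genes (4679 higher, 4045 lower) and that with SKI-I called 9706 (5068 higher, 4638 lower). Under quantile normalization the larger side turned in both (3902 higher and 4633 lower, and 4224 higher and 5291 lower).

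**Figure D1:**
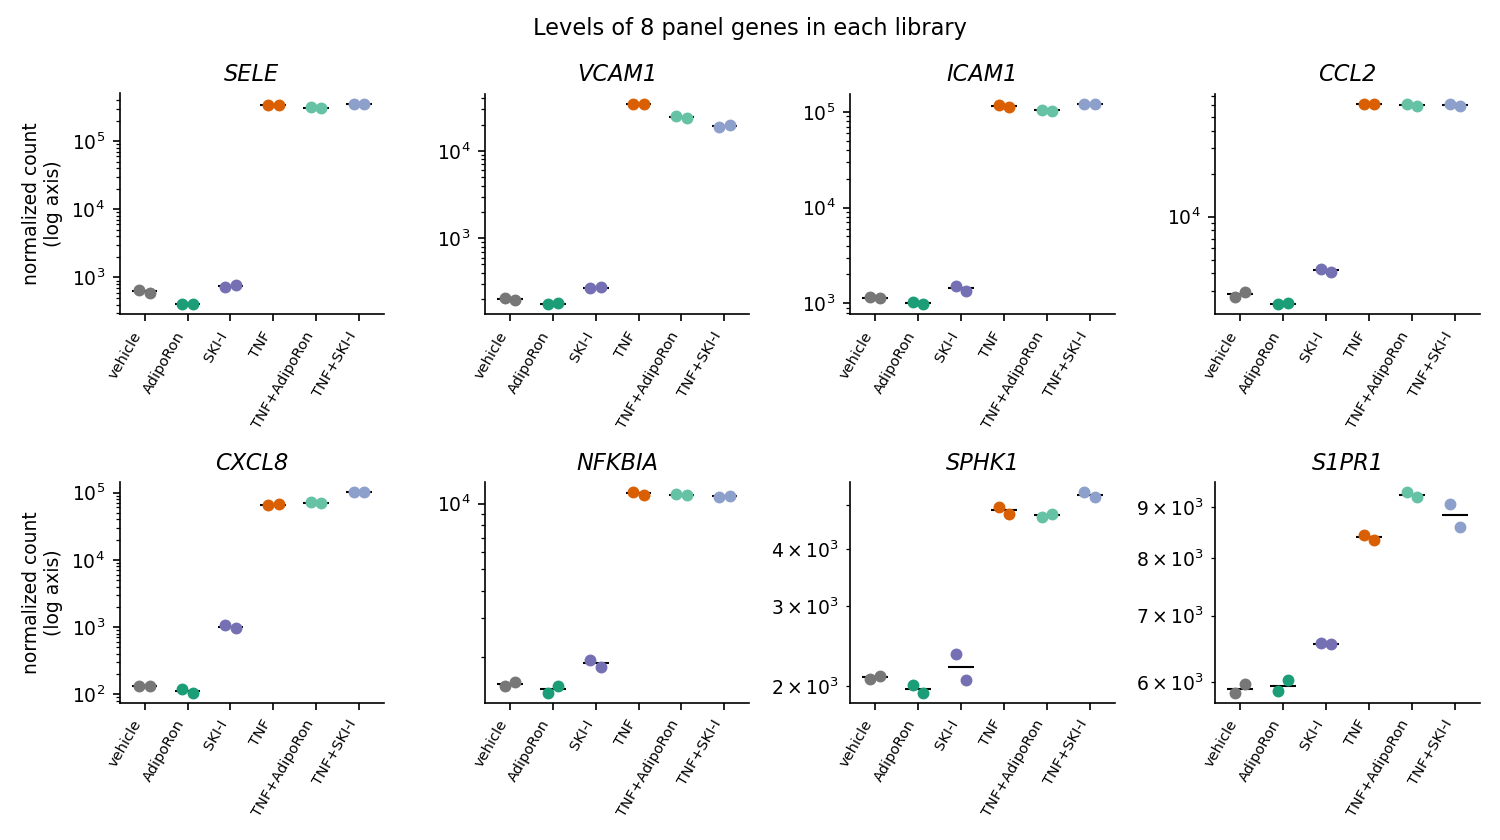
Normalized counts of 8 panel genes in each of the 12 libraries, on a log axis. Each point is 1 library, the short line is the mean of the 2 libraries of a group, and SELE goes from 632.7 in vehicle cells to 335900 with TNF-α while VCAM1 goes from 34890 with TNF-α alone to 24430 with AdipoRon added and 19380 with SKI-I added.

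The second comparison asked what AdipoRon did to cells without TNF-α. The thioredoxin-binding protein TXNIP (ENSG00000265972.6), whose transcription responds to glucose, fell from 3216 ± 1.81 to 1580 ± 3.26 normalized counts, a 2.03-fold drop (SD, n = 2, limma adjusted p = 0.000271). SELE was 1.57-fold lower, at 402 ± 0.183 against 632.7 ± 44.6, and the collagen gene COL12A1 was 1.51-fold lower (both adjusted p = 0.000271). VCAM1, ICAM1 and CXCL8 had log2 changes of -0.17, -0.20 and -0.24 that did not pass (adjusted p = 0.19, 0.118 and 0.109). The kinases SPHK1 and SPHK2 and the receptors S1PR1, ADIPOR1 and ADIPOR2 lay within 1.06-fold of vehicle, and none of them passed.

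Among the fixed lists, the ER chaperones moved most clearly with AdipoRon: 8 of 17 fell and none rose (9 fell when adjusted over the list alone), with a median log2 change of -0.17. HSPA5, the main ER chaperone, was 1.24-fold lower, at 20110 ± 509 against 24930 ± 96.7 normalized counts (SD, n = 2, adjusted p = 0.000558), and calreticulin (CALR) was 1.2-fold lower. This list passed camera with either correlation (adjusted p = 9.68e-13, and 0.0328 with an estimated one), the 1 list of 14 called that did so. The other 13 did not pass with an estimated correlation, among them leukocyte adhesion (2 of 19 fell, 6 adjusted over the list alone, median -0.10, adjusted p = 1.21e-05 and 0.0844 with an estimated correlation), smooth muscle and fibroblasts (1 of 12 fell, 5 adjusted over the list alone, 0.00125 and 0.0719), coagulation (3 of 21 fell, 7 adjusted over the list alone, 8.31e-05 and 0.0844) and heat shock (limma called 0 of 15, with 5 at an unadjusted p under 0.05 and 3 lower adjusted over the list alone, 0.00426 and 0.0844). The heat shock call also ended under quantile normalization (adjusted p = 0.387, median from -0.06 to -0.004). The interferon list had a median of 0.09 with 1 gene passing, MX2 (4 up and 4 down when adjusted over the list alone). Its call (adjusted p = 0.00556, and 0.569 with an estimated correlation) ended with only the groups compared (0.078). The call also ended without vehicle replicate 2 (median 0.074) or AdipoRon replicate 1 (median -0.02), so the list's direction rests on 1 library. The call of MX2 itself (limma adjusted p = 0.00831) ended without vehicle replicate 1 (0.0651) or AdipoRon replicate 2 (0.0684). Ribosomal protein genes shifted up by 0.05 and mitochondrial transcripts by 0.05 (adjusted p = 7.85e-06 and 0.00791, and 0.559 for both with an estimated correlation), and limma called 0 genes of either list, with 3 and 2 at an unadjusted p under 0.05. Without vehicle replicate 1 the call of the mitochondrial list ended (0.91) and its median turned to -0.03. In the sphingolipid list limma called 0 of 42 genes and in the adiponectin and AMPK list 0 of 18, also when adjusted over the list alone, with 5 and 1 at an unadjusted p under 0.05.

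Further lists called for AdipoRon were chemokines (3 of 30 fell, 6 down and 1 up adjusted over the list alone, adjusted p = 0.0171, and 0.186 with an estimated correlation), TNF superfamily (2 of 21 fell, 4 adjusted over the list alone, 0.0117 and 0.212) and endothelial identity (4 of 35 fell, 8 adjusted over the list alone, 0.000117 and 0.132). Matrix (3 of 27 fell and 2 rose, 10 and 2 adjusted over the list alone, 0.000252 and 0.249) and TGF-beta response (4 of 28 fell, 6 adjusted over the list alone, 0.0181 and 0.213) were called as well. The cell cycle list had a median of -0.12 (9.75e-05 and 0.212), and limma called 0 of its 36 genes with 7 at an unadjusted p under 0.05. Calls ended for endothelial identity, matrix and TGF-beta under quantile normalization (0.717, 0.477 and 0.106). With only the groups compared, calls ended for chemokines (0.109) and TGF-beta (0.079). They ended for chemokines without vehicle replicate 2 (0.283) or AdipoRon replicate 2 (0.065), for TNF superfamily without AdipoRon replicate 1 (0.0688) and for TGF-beta without vehicle replicate 2 (0.151).

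For AdipoRon limma called 127 genes, 14 higher and 113 lower, so 11% of the calls were higher, and quantile normalization gave 93 calls with 37.6% higher. Without vehicle replicate 1 or 2 it called 30 and 16, without AdipoRon replicate 1 or 2 it called 52 and 22, without TNF+SKI-I replicate 1 or 2 it called 72 each, and with only the vehicle and AdipoRon libraries fitted it called 2. Of the 20 genes named by size, TXNIP, SELE and COL12A1 kept their call in all 12 fits without 1 library, and SELE, COL12A1, HSPA5 and CALR lost it with only those 4 libraries fitted.

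The third comparison asked what AdipoRon did to cells that also received TNF-α. VCAM1 (ENSG00000162692.12) was 1.43-fold lower, at 24430 ± 885 against 34890 ± 129 normalized counts (SD, n = 2, limma adjusted p = 0.00147). TXNIP was again lower, by 2.04-fold (322.1 ± 45.5 against 653.4 ± 6.32), the interferon-induced HERC6 was 1.86-fold lower and the transporter ABCA4 2.03-fold lower. CD34 fell 1.3-fold, the death ligand TNFSF10 1.27-fold, the lipid carrier FABP4 1.39-fold and the chaperone HSPA8 1.26-fold, while the serine synthesis enzyme PSAT1 rose 1.36-fold. SELE, ICAM1, CCL2, CXCL8 and NFKBIA had log2 changes of -0.11, -0.15, -0.03, 0.08 and -0.02 and did not pass (adjusted p = 0.297, 0.184, 0.826, 0.589 and 0.92).

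The interferon response genes were lower as a group: 26 of 45 fell and none rose (42 fell when adjusted over the list alone), with a median log2 change of -0.54. IFIT1 stood at 2449 ± 390 against 4908 ± 18.3 normalized counts and RSAD2 at 2520 ± 282 against 4613 ± 360 (SD, n = 2), which did not pass over all genes (adjusted p = 0.0894 and 0.0944). The list passed camera with either correlation (adjusted p = 1.09e-41, and 0.0334 with an estimated one). The NF-kB list had a median of -0.03 with 1 gene higher of 28 (adjusted p = 0.331), and the chemokine list a median of -0.04 with 2 lower of 30 (3 adjusted over the list alone, adjusted p = 0.364). Tested against each other over their 73 genes, a test chosen after these results were seen, interferon genes were lower than NF-kB genes (camera p = 1.42e-14, and 0.00329 with an estimated correlation). In MHC class I antigen presentation 9 of 20 genes fell and none rose (16 fell adjusted over the list alone, median -0.19, adjusted p = 4.34e-17, and 0.0559 with an estimated correlation).

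ER chaperones and heat shock genes were also lower with AdipoRon under TNF-α. Of 17 ER chaperones 6 fell (11 adjusted over the list alone, median -0.15) and of 15 heat shock genes 4 fell (8 adjusted over the list alone, median -0.07), none rising in either list, and both passed camera with either correlation (adjusted p = 6.38e-09 and 2.94e-07, with an estimated correlation 0.0374 and 0.0328). Of 25 cholesterol genes 4 fell (15 adjusted over the list alone, median -0.14, adjusted p = 1.75e-12, and 0.0844 with an estimated correlation). In the ATF4 list 3 genes rose and 1 fell of 30 (14 rose and 2 fell when adjusted over the list alone), with a median of 0.16 (adjusted p = 2.02e-09, and 0.145 with an estimated correlation). The ribosomal protein list shifted up by 0.06 with 1 of 35 genes passing (adjusted p = 3.79e-08, and 0.467 with an estimated correlation).

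Leukocyte adhesion genes were lower in 4 of 19 (6 adjusted over the list alone, median -0.11, adjusted p = 8.31e-05, and 0.09 with an estimated correlation) and endothelial identity genes in 4 of 35 (4 adjusted over the list alone, median -0.08, 1.24e-06 and 0.0844), with none higher in either list. The adiponectin and AMPK list had a median of 0.07 (adjusted p = 0.0476, and 0.212 with an estimated correlation), and limma called 0 of its 18 genes with 3 at an unadjusted p under 0.05. Its call ended in 10 of the 12 fits without 1 library (0.052 to 0.169), that is in each but those without AdipoRon replicate 1 or 2. Fatty acid synthesis (1 of 15 fell, 3 adjusted over the list alone, 0.0321 and 0.155), matrix (2 of 27 fell, 5 down and 1 up adjusted over the list alone, 0.000432 and 0.257) and NRF2 (1 of 18 rose, also over the list alone, 0.00367 and 0.441) were called too. Calls ended for fatty acid synthesis and matrix under quantile normalization (0.537 and 0.363). With only the groups compared, calls ended for fatty acid synthesis (0.0644) and for adiponectin and AMPK (0.0894), the latter also with a pseudocount of 5 (0.0566). They ended for fatty acid synthesis without TNF replicate 1 (0.0553), TNF replicate 2 (0.0787) or TNF+AdipoRon replicate 1 (0.0913), and for NRF2 without TNF replicate 2 (0.18).

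Adding AdipoRon to TNF-α called 285 genes in limma, 63 higher and 222 lower, so 22.1% of the calls were higher, and quantile normalization gave 212 calls with 41.5% higher. It called 64 genes without TNF replicate 1, 166 without TNF replicate 2, 96 and 64 without TNF+AdipoRon replicate 1 and 2, and 149 with only those 4 libraries fitted. Of the 20 genes named by size, TXNIP, ABCA4 and HERC6 kept their call in all 12 fits without 1 library, as did VCAM1, CD34, TNFSF10, FABP4, HSPA8 and PSAT1.

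**Figure D2:**
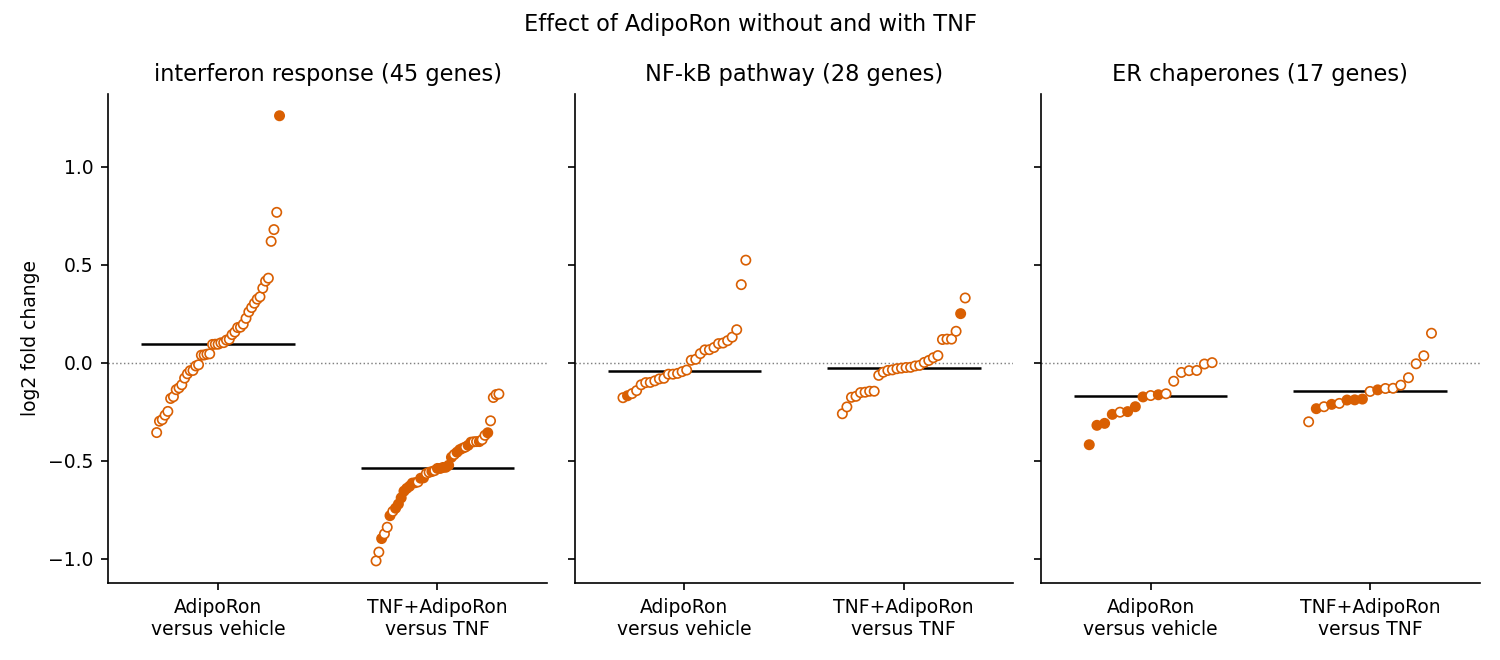
Log2 fold change with AdipoRon of each gene of 3 fixed lists, without TNF-α (AdipoRon against vehicle) and with it (TNF+AdipoRon against TNF). Each circle is 1 gene, filled where it passed an adjusted p of 0.05 in limma, and the line is the list's median, which for the 45 interferon response genes went from 0.09 without TNF-α to -0.54 with it.

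The difference between the effect of AdipoRon with and without TNF-α was tested as an interaction. MX2 had an interaction of -2.04 ± 0.237 on the log2 scale (SE), IFIT3 of -1.02 ± 0.116 and SP110, an interferon-induced nuclear body gene, of -0.87 ± 0.10 (limma adjusted p = 0.00999 for each). MX2 was called higher with AdipoRon alone, from a low level in vehicle cells, and lower under TNF-α, so its interaction holds both changes. SELE had an interaction of 0.54 ± 0.066 (SE, adjusted p = 0.0102): it was 1.57-fold lower with AdipoRon alone and 1.08-fold lower under TNF-α. Of the 45 interferon response genes 9 had a lower interaction and none a higher one (37 lower when adjusted over the list alone), with a median of -0.62 (camera adjusted p = 2.75e-44, and 0.0328 with an estimated correlation). VCAM1 did not pass (-0.35 ± 0.071, adjusted p = 0.0967). The interaction called 36 genes, 11 higher and 25 lower. It called 0 without TNF replicate 1 or TNF+AdipoRon replicate 2, where limma gave 1374 and 1286 genes with an unadjusted p under 0.05. The calls of MX2, IFIT3, SP110 and SELE each ended there, and that of SELE also without TNF+AdipoRon replicate 1. It called 8 without vehicle replicate 1 or TNF+AdipoRon replicate 1, 13 without vehicle replicate 2 or AdipoRon replicate 1, 17 and 18 without TNF+SKI-I replicate 1 and 2, 23 without TNF replicate 2, and 18 with only the 8 libraries of the interaction fitted.

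Whether AdipoRon shifted the TNF-α response as a whole was tested on genes chosen with other libraries. The 1409 genes that rose at least 2-fold with TNF-α among SKI-I-treated cells had a median log2 change of -0.09 with AdipoRon under TNF-α, with 972 lower and 436 higher (of those called, 94 lower and 4 higher), and passed camera with either correlation (adjusted p = 1e-09, and 0.0183 with an estimated one, over 4 sets). The 1514 genes that fell at least 2-fold had a median of 0.04, with 650 lower and 864 higher. Of those called, 7 were lower and 4 higher, against the direction of the median. Camera gave p = 0.0424 (adjusted p = 0.0849, and 0.0323 with an estimated correlation), so the call of this set depends on the setting. For both sets the tests and calls used a fit of the TNF and TNF+AdipoRon libraries alone, in which the median over all tested genes was -0.008. Interferon and MHC class I genes were not taken out of either set, so the shift of the first set need not be general.

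The fourth comparison asked what SKI-I did to cells without TNF-α. ANGPTL4, a lipase inhibitor induced by low oxygen and fatty acids, rose 11.9-fold from 39.4 ± 6.22 to 482.6 ± 94.6 normalized counts (SD, n = 2, limma adjusted p = 4.67e-07). The noncoding host gene MIR210HG rose 7.60-fold, ANKRD37 5.90-fold, the asparagine synthetase ASNS 8.30-fold, STC2 6.37-fold and the peptide hormone gene ADM2 11.4-fold. CXCL8 rose 7.57-fold, from 132.2 ± 0.962 to 1009 ± 65.4, and PTGS2 rose 3.44-fold (SD, n = 2). VCAM1 rose 1.36-fold, CCL2 1.48-fold and SELE 1.18-fold. The mitochondrial carrier UCP2 was 3.29-fold lower, the myosin MYO7A 3.31-fold lower and the drug transporter ABCB1 3.23-fold lower.

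All 17 ER chaperones rose with SKI-I (median 0.93), HSP90B1 by 2.83-fold from 42440 ± 685 to 120100 ± 409 normalized counts and HYOU1 by 2.69-fold (SD, n = 2). In the ATF4 list 27 of 30 genes rose and none fell (29 and 1 adjusted over the list alone, median 1.08), with ATF3 4.80-fold and CHAC1 4.26-fold higher. Of 25 hypoxia and glycolysis genes 24 rose and none fell (25 rose adjusted over the list alone, median 0.61), with the glucose transporter SLC2A1 3.20-fold, VEGFA 2.98-fold and EGLN3 5.49-fold higher. Of 36 cell cycle genes 29 rose and 1 fell (median 0.81), CDC6 by 3.31-fold and RRM2 by 2.52-fold, and of 28 NF-kB genes 14 rose and 1 fell (18 and 2 adjusted over the list alone, median 0.28). Heat shock genes went the other way, with 11 of 15 lower and none higher (12 lower adjusted over the list alone, median -0.21), HSPA1A by 1.81-fold. These 6 lists passed camera with either correlation (adjusted p = 1.01e-28, 7.51e-32, 3.23e-27, 3.66e-20, 1.36e-07 and 1.25e-08, with an estimated correlation 0.0181, 0.0328, 0.0334, 0.0328, 0.046 and 0.023).

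Of the other lists with SKI-I, 14 of 25 cholesterol genes rose (18 rose and 1 fell adjusted over the list alone, median 0.25, adjusted p = 9.72e-09, and 0.134 with an estimated correlation), and 16 of 27 p53 targets rose and 2 fell (18 and 4 adjusted over the list alone, median 0.29, 1.24e-06 and 0.127). Ribosomal protein genes were higher in 13 of 35 (17 adjusted over the list alone), by a median of 0.11 (adjusted p = 2.93e-06, and 0.541 with an estimated correlation), and this list's call ended under quantile normalization (adjusted p = 0.356). The sphingolipid list, which holds both sphingosine kinases, had 9 genes higher and 7 lower of 42 (10 and 8 adjusted over the list alone). It did not pass (camera adjusted p = 0.664). In it the ceramidase ACER2 rose 2.01-fold, while SPHK1 and SPHK2 had log2 changes of 0.07 and -0.06 and did not pass (adjusted p = 0.449 and 0.743). The interferon list did not pass (5 higher and 10 lower of 45, 6 and 12 adjusted over the list alone, adjusted p = 0.225).

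The remaining lists called for SKI-I were chemokines (10 of 30 rose and 3 fell, 13 and 5 adjusted over the list alone, adjusted p = 0.0298, and 0.212 with an estimated correlation) and TNF superfamily (8 of 21 rose and 4 fell, 9 and 4 adjusted over the list alone, 0.0402 and 0.285). The matrix list was called too (11 of 27 rose and 4 fell, 11 and 6 adjusted over the list alone, 0.0298 and 0.488). With only the groups compared, each of these calls ended (0.0937 for chemokines, 0.0727 for TNF superfamily and 0.0808 for matrix). That of TNF superfamily also ended with a pseudocount of 5 (0.0648), where its median was 0.278 against 0.439. Calls ended for chemokines without vehicle replicate 1 (0.0539) or SKI-I replicate 2 (0.0599), and for TNF superfamily without TNF replicate 1 (0.0548), TNF replicate 2 (0.0561) or SKI-I replicate 1 (0.0835). They ended for matrix without vehicle replicate 1 (0.0723) or SKI-I replicate 1 (0.0584) and under quantile normalization (0.647).

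For SKI-I limma called 2909 genes, 1703 higher and 1206 lower, so 58.5% of the calls were higher, and quantile normalization gave 3047 calls with 48.4% higher. It called 1687 without vehicle replicate 1, 1701 without vehicle replicate 2, 1902 without SKI-I replicate 1 and 1849 with only those 4 libraries fitted, where VCAM1 and SELE lost their call. Of the 20 genes named by size 17 kept their call in all 12 fits without 1 library.

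The fifth comparison asked what SKI-I did to cells that also received TNF-α. ANGPTL4 rose 81.0-fold, from 44.4 ± 4.13 to 3677 ± 439 normalized counts, and SLC2A1 rose 11.5-fold, from 1111 ± 25.3 to 12840 ± 1160 (SD, n = 2, limma adjusted p = 2.98e-09 and 1.03e-10). PPFIA4, a scaffold protein gene, went from 0.478 ± 0.677 to 1107 ± 252, MIR210HG rose 65.5-fold, the adenylate kinase AK4 10.7-fold, EGLN3, a prolyl hydroxylase that acts on hypoxia-inducible factor, 9.91-fold and the enolase ENO2 7.69-fold. VCAM1 was 1.80-fold lower, at 19380 ± 666 against 34890 ± 129, while CXCL8 rose further by 1.53-fold to 101200 ± 870 (SD, n = 2). The granulocyte growth factor CSF3 was 3.99-fold lower, IL6 2.68-fold, the nitric oxide synthase NOS3 2.28-fold and the lymphatic marker LYVE1 3.72-fold lower. SELE, ICAM1, CCL2 and NFKBIA had log2 changes of 0.06, 0.08, -0.02 and -0.04 and did not pass (adjusted p = 0.365, 0.292, 0.821 and 0.552).

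All 25 hypoxia and glycolysis genes rose with SKI-I under TNF-α, with a median log2 change of 1.68, among them BNIP3 by 7.56-fold. Of 17 ER chaperones 13 rose and none fell (14 rose adjusted over the list alone, median 0.35), HSP90B1 by 1.88-fold, and 12 of 15 heat shock genes fell and none rose (13 fell adjusted over the list alone, median -0.38), HSPH1 by 1.58-fold. These 3 lists passed camera with either correlation (adjusted p = 3.8e-32, 1.52e-09 and 2.76e-09, with an estimated correlation 0.0328, 0.0343 and 0.0216). Of 30 ATF4 genes 22 rose (median 0.46, adjusted p = 1.06e-11, and 0.106 with an estimated correlation), and of 36 cell cycle genes 26 rose and 2 fell (median 0.63, 2.02e-09 and 0.0844). In endothelial identity 19 of 35 rose and 9 fell (20 and 10 adjusted over the list alone, median 0.23, 0.00232 and 0.212), with PTPRB 1.91-fold and DLL4 1.76-fold higher and the apelin receptor APLNR 6.26-fold lower, and this list's call ended under quantile normalization (adjusted p = 0.181). Ribosomal protein genes were higher in 25 of 35 (30 adjusted over the list alone), by a median of 0.16 (3.13e-09, and 0.449 with an estimated correlation). The p53 list (14 of 27 rose and 2 fell, 15 and 3 adjusted over the list alone, 5.06e-05 and 0.192) and the matrix list (11 of 27 rose and 5 fell, also over the list alone, 0.0275 and 0.479) were called too. The matrix call ended without TNF replicate 2 (0.0715) or TNF+SKI-I replicate 2 (0.076) and under quantile normalization (0.896). The chemokine list, with 2 higher and 10 lower of 30, did not pass (adjusted p = 0.0508).

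Adding SKI-I to TNF-α called 5255 genes in limma, 2698 higher and 2557 lower, 368 and 336 of them by at least 2-fold, and under quantile normalization the larger side turned (2157 higher and 2556 lower). Of the 20 genes named by size 17 kept their call in all 12 fits without 1 library. The TNF-α response as a whole, measured on genes chosen with the AdipoRon libraries, showed no net shift that passed. The 1348 genes that rose with TNF-α had 674 lower and 673 higher with SKI-I (camera adjusted p = 0.649). The 1512 that fell had a median of -0.07 with 830 lower and 680 higher (adjusted p = 0.463). Single genes did move, both ways. With the TNF and TNF+SKI-I libraries alone fitted, limma called 237 lower and 285 higher in the first set, and 152 lower and 142 higher in the second.

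**Figure D3:**
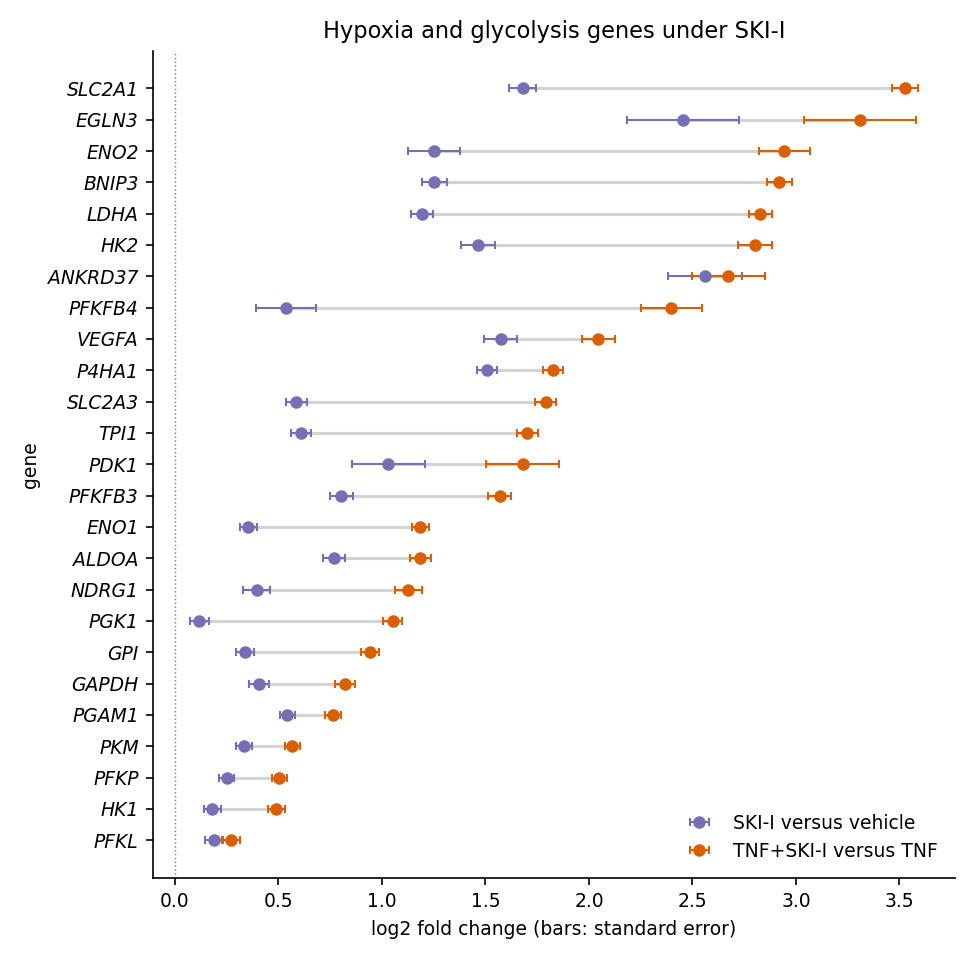
Log2 fold change with SKI-I of the 25 measured hypoxia and glycolysis genes, without TNF-α (SKI-I against vehicle) and with it (TNF+SKI-I against TNF). Points are limma estimates from 2 libraries per group and bars are standard errors, and the median of the list went from 0.61 without TNF-α to 1.68 with it.

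The difference between the effect of SKI-I with and without TNF-α was tested as an interaction. ANGPTL4 had an interaction of 2.76 ± 0.270 and MIR210HG of 3.11 ± 0.299 on the log2 scale (SE, limma adjusted p = 0.000154 and 0.000137). Of 25 hypoxia and glycolysis genes 21 had a higher interaction and none a lower one (22 higher adjusted over the list alone, median 0.73). CXCL8, VCAM1 and CCL2, raised by SKI-I alone, had interactions of -2.31 ± 0.085, -1.29 ± 0.071 and -0.58 ± 0.060 (SE, limma adjusted p = 9.58e-08, 2.43e-06 and 0.000229). ADM2 and RCAN1 had -2.98 ± 0.138 and -2.63 ± 0.077. These values compare folds, and CXCL8 itself still rose with SKI-I under TNF-α. Of 30 chemokines and cytokines 10 had a lower interaction and none a higher one (13 and 2 adjusted over the list alone, median -0.81), and 14 of 17 ER chaperones were lower (15 adjusted over the list alone, median -0.59). These 3 lists passed camera with either correlation (adjusted p = 3.8e-32, 2.98e-07 and 9.23e-24, with an estimated correlation 0.0328, 0.0334 and 0.0181). The interaction called 967 genes, 488 higher and 479 lower (408 and 441 under quantile normalization), with 589 and 498 without vehicle replicate 1 and 2 and 644 without TNF replicate 1.

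**Figure D4:**
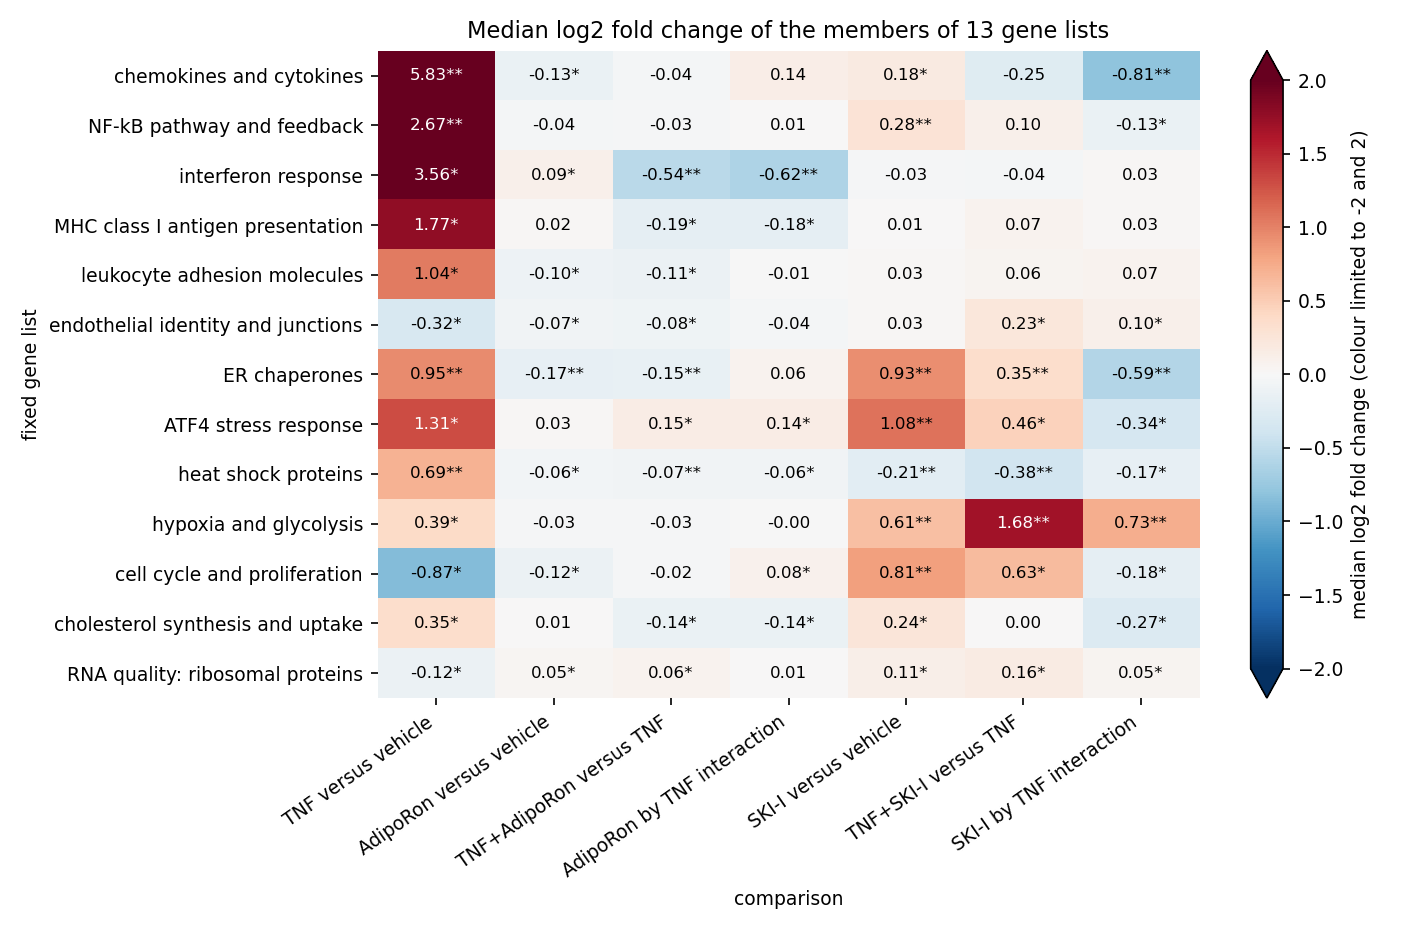
Median log2 fold change of the measured members of 13 fixed gene lists in 7 comparisons, printed in each cell and shown as colour limited to -2 and 2. A single asterisk marks lists that passed camera at an adjusted p of 0.05 with the preset correlation and a double asterisk those that also passed with an estimated correlation, as the hypoxia list did with SKI-I (0.61) and with SKI-I under TNF-α (1.68).

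The last comparison set the compounds against each other, both at 5 µM. Without TNF-α, SELE was higher with SKI-I than with AdipoRon by 0.89 ± 0.047 on the log2 scale, VCAM1 by 0.61 ± 0.050, ICAM1 by 0.52 ± 0.051 and CXCL8 by 3.17 ± 0.060 (SE, n = 2 per group, limma adjusted p = 3.5e-07, 7.96e-06, 3.44e-05 and 6.84e-11). Under TNF-α, VCAM1 was lower with SKI-I than with AdipoRon by a log2 difference of -0.33 ± 0.050 (adjusted p = 0.000442), CXCL8 was higher by 0.53 ± 0.060 and ICAM1 by 0.23 ± 0.051 (adjusted p = 6.63e-05 and 0.00508). CCL2 differed by 0.01 ± 0.043 under TNF-α and did not pass (adjusted p = 0.842). Without TNF-α limma called 3056 genes between the compounds, 1989 higher with SKI-I and 1067 lower, so 65.1% were higher against 48.2% of 3188 under quantile normalization, and it called 1962 and 1905 without AdipoRon replicate 1 and 2. Under TNF-α it called 5561, with 2964 higher and 2597 lower with SKI-I, and under quantile normalization the larger side turned (2256 higher and 2712 lower).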

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

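Of the tests in this part, that of interferon against NF-kB genes was chosen after the result was seen, the patterns to weigh were chosen after the list results were seen, and the tests of scaling, of single libraries and of low values were written before their own results were seen. Each result below drew attention because a compound's effect differed between cells with and without TNF-α by an interaction test.

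The interaction of AdipoRon with TNF-α called 36 genes, 0 without TNF replicate 1 or TNF+AdipoRon replicate 2 (limma, 1374 and 1286 at an unadjusted p under 0.05), 8 without vehicle replicate 1 or TNF+AdipoRon replicate 1, 13 without vehicle replicate 2 or AdipoRon replicate 1, 17 and 18 without TNF+SKI-I replicates 1 and 2, and 23 without TNF replicate 2. The genes named by size had log2 interactions of 1.141 (TAGLN), 0.713 (VEGFA), 0.570 (CRNKL1), 0.539 (SELE), 0.456 (ANKRD1), -2.124 (CXCL10), -2.042 (MX2), -1.024 (IFIT3), -0.873 (SP110) and -0.863 (IL18BP), and none kept its call in all 12 fits without 1 library. Its called lists had medians of -0.618 (interferon response), -0.185 (MHC class I), -0.140 (cholesterol), -0.088 (fatty acid synthesis), 0.144 (ATF4), -0.063 (heat shock) and 0.084 (cell cycle). The cell cycle call ended without vehicle replicate 1 (median 0.045), TNF replicate 2 (0.063), AdipoRon replicate 2 (0.068) or TNF+AdipoRon replicate 2 (0.051). Of these the interferon list passed with an estimated correlation (adjusted p = 0.0328).

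The interaction of SKI-I with TNF-α called 967 genes, 589 and 498 without vehicle replicates 1 and 2 and 644 without TNF replicate 1. The genes named by size had log2 interactions of 5.541 (PPFIA4), 3.106 (MIR210HG), 2.763 (ANGPTL4), 2.631 (ABCB1), 2.491 (TCAF2), -2.977 (ADM2), -2.935 (BHLHA15), -2.714 (CXCL10), -2.627 (RCAN1) and -2.613 (ARHGAP33). BHLHA15 lost its call in 10 of 12 fits without 1 library, and ARHGAP33 lost it without vehicle replicate 2, TNF replicate 1, SKI-I replicate 1 or TNF+SKI-I replicate 1. Of the panel, VCAM1 (-1.294), CCL2 (-0.578), CXCL8 (-2.311) and NFKBIA (-0.356) passed, and NFKBIA lost its call without vehicle replicate 1 (0.0622) or TNF replicate 1 (0.0566). Its called lists had medians of -0.809 (chemokines), -0.126 (NF-kB), -0.251 (TNF superfamily), 0.097 (endothelial identity), 0.123 (AMPK), -0.272 (cholesterol), -0.339 (ATF4), -0.591 (ER chaperones), -0.171 (heat shock), -0.176 (cell cycle), 0.733 (hypoxia) and 0.051 (ribosomal proteins). The ribosomal call ended without TNF replicate 2 (median 0.019, adjusted p = 0.122), SKI-I replicate 2 (-0.008, 0.543) or TNF+SKI-I replicate 1 (0.012, 0.201) and under quantile normalization (0.012, 0.222), and that of endothelial identity under quantile normalization (0.052, 0.233). The AMPK call ended without vehicle replicate 1 (0.0573), TNF replicate 1 (0.061), SKI-I replicate 1 (0.161, median 0.057) or TNF+SKI-I replicate 2 (0.0616). The TNF superfamily call ended without TNF replicate 1 (0.104, median -0.18), SKI-I replicate 1 (0.0998) or TNF+SKI-I replicates 1 and 2 (0.0529 and 0.0691). Of the lists the hypoxia, chemokine and ER chaperone lists passed camera with an estimated correlation (adjusted p = 0.0328, 0.0334 and 0.0181). The chemokine list was not put through the tests of scaling, single libraries and low values below.

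The interferon response genes shifted down with AdipoRon under TNF-α (median -0.54) and had no stable direction without it (0.09, and -0.023 without AdipoRon replicate 1), a median interaction of -0.618. After quantile normalization the median was -0.576, the weakest of 8 fits without 1 library gave -0.544 (without AdipoRon replicate 1), and the 38 members with at least 50 normalized counts in each of the 8 libraries gave -0.566. Each value lies close to the shift itself, which argues against a scaling of whole libraries, 1 library and low values as its whole cause. Quantile normalization cannot undo a factor per gene and library, so that part of the authors' scaling was not tested. AdipoRon may act on the interferon part of the TNF-α response, or TNF-α may have acted more weakly in both combined libraries. Under TNF-α the NF-kB and chemokine lists had medians of -0.03 and -0.04 with AdipoRon. Interferon genes were lower than NF-kB genes (camera p = 1.42e-14, and 0.00329 with an estimated correlation). The 1409 genes that TNF-α raised had a median of -0.09, with interferon genes not taken out of that set. A weaker action of TNF-α stays open if NF-kB genes were saturated.

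The hypoxia and glycolysis genes were raised by SKI-I more with TNF-α than without it (median interaction 0.733). After quantile normalization the median was 0.650, and the weakest fit without 1 library gave 0.698 (without TNF replicate 1). The 23 members with at least 50 normalized counts gave 0.733. These values argue against a scaling of whole libraries, 1 library and low values as the whole cause of the difference. A factor per gene and library was again not tested. SKI-I may raise these genes more when TNF-α is present, and a difference in oxygen or cell density between the wells was not tested.

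The ER chaperones were raised by SKI-I less with TNF-α than without it (median interaction -0.591). After quantile normalization the median was -0.673 and the weakest fit without 1 library gave -0.525 (without TNF+SKI-I replicate 1). These values argue against a scaling of whole libraries and 1 library as the whole cause of the difference. A factor per gene and library was again not tested. All 17 members had at least 50 normalized counts in each of the 8 libraries, so the filter removed none and the median stayed at -0.591. That median adds nothing, but the absence of low members argues against low values as the cause. TNF-α alone had raised this list by a median of 0.953, so a ceiling on these genes may explain the smaller rise and was not tested.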

How the results depend on the processing

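The alternatives here were chosen before the data were examined, except that the adjustment of the TNF-α response sets was chosen later. Of 471 calls of named genes, each 1 gene in 1 comparison, 464 held with a pseudocount of 5 and 450 with no filter. Quantile normalization kept 427, only the groups compared 368, the replicate block 447 and robust variances 465. Of 83 list calls, each 1 list in 1 comparison, 81, 83, 69, 75, 83 and 83 held in the same order. With an estimated correlation 22 held. The estimated correlation left 5 lists with TNF-α, 1 with AdipoRon, 6 with SKI-I, 3 with AdipoRon under TNF-α, 3 with SKI-I under TNF-α and 1 and 3 in the interactions of AdipoRon and SKI-I; the cause was not tested. With only the groups compared, which leaves fewer libraries to estimate the spread, limma called 2 genes for AdipoRon, 1849 for SKI-I, 149 for AdipoRon under TNF-α and 18 in its interaction. Under quantile normalization the mitochondrial transcripts MT-ND2 and MT-ATP6 reversed with TNF-α (-0.042 and -0.123, against 0.31 and 0.252) and MT-ND4 with SKI-I under TNF-α (-0.102, against 0.163); the cause was not tested. A list's direction is that of its test against other genes. The medians behind 5 list calls changed sign where the call ended. Under quantile normalization these were matrix and proteases with SKI-I (-0.021) and with SKI-I under TNF-α (-0.042). Mitochondrial transcripts with AdipoRon turned without vehicle replicate 1 (-0.028), and interferon response with AdipoRon without AdipoRon replicate 1 (-0.023). Ribosomal proteins in the SKI-I interaction turned without SKI-I replicate 2 (-0.008). The cause was not tested. Without 1 library the calls ranged from 16 (without vehicle replicate 2) to 139 for AdipoRon, 1687 (without vehicle replicate 1) to 2901 for SKI-I, 64 (without TNF replicate 1 or TNF+AdipoRon replicate 2) to 275 for AdipoRon under TNF-α, 0 (without TNF replicate 1 or TNF+AdipoRon replicate 2, with 1374 and 1286 at an unadjusted p under 0.05 in limma) to 43 in its interaction, 498 (without vehicle replicate 2) to 864 in that of SKI-I, and 1905 (without AdipoRon replicate 2) to 3073 between the compounds, where a lone library is assumed to vary like the other groups. The other libraries that moved these counts are given with each comparison. TNF-α itself ranged from 7748 to 9177 and SKI-I under TNF-α from 3740 to 5273. No pairing by replicate number was seen (2 of 15 pairs of groups correlated over 0.1, range -0.116 to 0.135). A shared origin with little effect on expression is not excluded by that. The replicate block gave 9064 calls for TNF-α, 115 for AdipoRon and 2839 for SKI-I. Results past the threshold in neither fit count as kept even where their sign changed. The planned count test was not run, since whole reads could not be recovered. Depth limits genes near 10 normalized counts, where 1 read was worth roughly 0.8001 to 1.32.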

Other observations

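The 3 tests in this part were chosen after the results they follow were seen, and about 45 further genes were viewed before they were picked, without tests of other ideas.

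Interferon genes and NF-kB genes both rose with TNF-α, and AdipoRon may lower the former more than the latter. Over the 73 genes of both lists, interferon genes were lower than NF-kB genes with AdipoRon under TNF-α (medians -0.54 and -0.03, camera p = 1.42e-14, and 0.00329 with an estimated correlation). The same libraries gave the idea and the test, and NF-kB genes near saturation would give the same result.

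SKI-I may act on targets of hypoxia-inducible factor as a class. A second list of 15 such targets was written, of which 13 were tested because ADM and LOX stood in fixed lists already. Its median was 0.52 with SKI-I (10 of 13 higher, camera adjusted p = 3.3e-10), 1.31 with SKI-I under TNF-α (12 higher, 3.36e-16) and 0.634 in the interaction (10 higher, 4.61e-18), over 6 tests. With TNF-α alone it was -0.18 (4 higher and 6 lower, adjusted p = 0.846), and with AdipoRon under TNF-α 0.06 (2 higher, 0.00199). FAM162A, MXI1 and BNIP3L, members of that list named after their values were seen, had log2 changes of 2.56, 1.94 and 1.92 with SKI-I under TNF-α.

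TXNIP was lower with AdipoRon with and without TNF-α, and a candidate explanation is a lower activity of its glucose-sensing regulator MondoA, which also drives ARRDC4. ARRDC4 had log2 changes of -0.850 ± 0.173 without TNF-α and -0.382 ± 0.173 with it (SE, limma adjusted p = 0.0531 and 0.341). Neither passed and both were negative, so the data do not decide.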
